A study of Rattus norvegicus with 20 samples.

How the data were processed

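The deposited array files hold, per the file headers, intensity values from Agilent Feature Extraction 9.5.3.1 for a 1-colour rat array with probe coordinates on rn4. The submitters name Feature Extraction 9.5 in their notes. The deposited intensity used was the processed signal, which the authors' software had background-subtracted and detrended on each array without scaling between arrays. The authors' deposited table holds a signed fold change and a p-value per probe for each compound, and per the file headers each block compares 1 compound with control. The tool behind the authors' p-value is not stated. Each array has 45018 spots, 1639 of them control spots, and 41012 probes, of which 263 have 10 spots.

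Spots marked as non-uniform or population outliers were set aside, a step decided after the files were seen. Values of repeated spots were averaged on the log2 scale, and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on every array of at least 1 group, which left 28133 probes. For each gene name the probe with the highest mean signal was tested, which left 24276 genes, and 23956 had values in the control group. Accessions of 10768 probes matched the deposited symbol table, 6780 kept genes were named through it, and 9694 have a symbol.

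Before groups were averaged, all 190 pairs of arrays were compared over 17133 probes well above background on all arrays, against the noise of 149 probes with 10 spots. MEHP replicates 1 and 2 were averaged, which left 19 samples. The number of arrays limits the precision of every estimate. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all samples with empirical Bayes variance (14 residual and 2.53 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each comparison. Files were read with the R package data.table in version 1.17.8.

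A gene was called at an adjusted p under 0.05. The 18 gene lists were fixed before the data were examined, along with the comparisons, the filter, the scaling and the alternative settings. The lists were steroidogenesis, cholesterol synthesis and uptake, fetal Leydig cell markers other than enzymes, Sertoli, gonocyte, peritubular and interstitial, endothelial, macrophage and leukocyte, erythroid, mesonephric duct and epididymal, and adrenal cortex markers, fatty acid oxidation and PPAR alpha targets, fatty acid synthesis, immediate early genes, endoplasmic reticulum stress, oxidative stress and xenobiotic response, cell cycle, and retinoid handling. camera with a preset correlation of 0.01 tested the 17 lists with at least 5 measured genes over 23817 genes complete in all samples. camera with an estimated correlation and fry stand beside it, and counts adjusted over the list alone use the genes of 1 list. Genes named in the text were those fixed beforehand, the genes with the largest fold changes each way among called genes with a symbol and complete separation of the arrays (or the 8 smallest p-values where fewer than 5 passed), and up to 4 members of each list with the largest fold change. Further members are named as examples of calls adjusted over the list alone. Where a gene was not well above background on all arrays of both groups, a lower bound of its fold replaces the estimate.

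The alternatives fixed then were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, no filter, a filter on all 20 arrays, all probes, a trended robust variance, a fit of the arrays of the 2 groups, replicate number as a block, a 2-fold threshold and leaving out each array in turn. Alternatives added after the data were seen were MEHP 1 and 2 as separate samples, control 2 and MEHP 3 left out, outlier spots kept, arrays weighted by arrayWeights, the 75th percentile over probes detected on all arrays, MEHP 3 and 4 left out, MEHP 1 and 2 left out together, EHO 1 and 2 left out, and the MEHP arrays left out of the fit. Calls shared through the common controls were compared with 50 simulations of unchanged groups and with 6 ways to split the controls. Labels were permuted over 35 splits of each pair of groups, and list means per sample were compared by exact permutation with an interval from variance pooled over the 5 groups.

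In a self-test values were simulated from each gene's own mean and residual spread, and 200 of 23956 genes were made different. At 2-fold the share recovered was 64.2% for DEHP, 59.7% for MEHP, 53.7% for TOTM and 47.8% for EHO, and 4.42% to 6.03% of calls were unchanged genes. Each share rests on 67 simulated genes, so these shares do not tell the compounds apart. The simulated noise was independent between genes and alike on all arrays. Weights of the real arrays ran from 0.065 for EHO 1 to 9.46 for MEHP 4, so the shares do not give the power of the real tests. The single list that was shifted passed camera, and 0 of 19 unshifted lists did. The scanner images and the probe sequences were not used here.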

Results

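The arrays profiled testes of rat foetuses whose dams were gavaged with corn oil, DEHP (di(2-ethylhexyl) phthalate), MEHP (mono(2-ethylhexyl) phthalate), TOTM (tris(2-ethylhexyl) trimellitate) or a compound labelled only EHO. The 4 compounds were given at 500 mg/kg on gestation days 12 to 19, so the doses were equal by mass and not by mole. Each of 20 arrays held a pool of testes from at least 3 pups of 1 litter, with 4 arrays per group. MEHP replicates 1 and 2 differed by less than the sampling noise and were counted as 1 sample, which leaves n = 3 for MEHP and n = 4 elsewhere. Their difference was 0.780 times the noise between repeated spots of 1 array, against a median of 2.30 times for pairs of arrays from 1 group. The p-values of single genes measure only the spread between these litter pools, with variance pooled over the 5 groups. Those of camera set the genes of a list against all other genes and rest on its preset correlation of 0.01. Each group was hybridised on its own slide and scanned with it, so slide and compound cannot be told apart in any comparison below.

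Between 46.1% and 63.5% of spots were well above background on the EHO arrays, against 63.9% to 79.8% on all the others. The limma fit covered 24276 genes, of which 23956 could be tested against control. Cyp17a1, the 17-hydroxylase that leads to androgens, could not: its spot was marked non-uniform on all 4 control arrays. Its log2 level was 6.75 ± 0.07 with TOTM (n = 4), 6.43 ± 0.33 with EHO (n = 4), 5.69 ± 0.53 with DEHP (n = 4) and 5.41 ± 1.17 with MEHP (n = 3). Fold changes are log2 with their standard error, levels are log2 relative to the 75th percentile of the array with their SD, and a gene is said to rise or fall only at an adjusted p under 0.05.

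**Figure D1:**
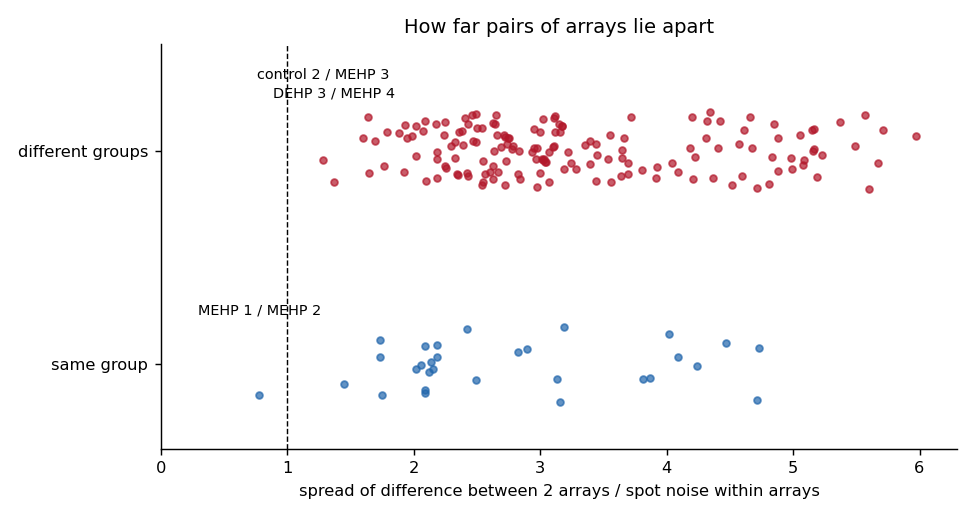
Difference between each pair of the 20 arrays, as a multiple of the noise between repeated spots of the same array. Pairs within a group and between groups are drawn separately.

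Genes that make and import cholesterol, the substrate of foetal androgen synthesis, were lower with DEHP. Of 21 such genes tested, 20 lay below control, with a median of −0.43 and a mean of −0.50 (camera adjusted p = 2.4e-26). With an estimated correlation the adjusted p = 0.00562. None of the 21 passed over all genes, and 14 were lower when adjusted over the list alone. Among these were Tm7sf2, a sterol reductase (−1.72 ± 0.30), Cyp51, which demethylates lanosterol (−1.05 ± 0.24), Ebp, a sterol isomerase (−0.95 ± 0.20), and Insig1, a sterol sensor (−0.90 ± 0.27). Hmgcs1 was at −0.87 ± 0.24 and Idi1 at −0.81 ± 0.18. Averaged over the list, each DEHP litter pool lay below every control pool (0.960 ± 0.13 against 1.46 ± 0.14, n = 4 each, exact permutation p = 0.0286).

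The steroidogenesis list was lower with DEHP (adjusted p = 0.00109), and this call was lost with an estimated correlation (adjusted p = 0.204). Its median over 13 genes was −0.11 and its mean −0.44, because a few genes carried most of the difference. Star, which moves cholesterol into mitochondria, averaged 1.77 ± 0.44 with DEHP and 3.30 ± 0.25 in control (n = 4 each), a difference of −1.53 ± 0.46. Scarb1, the receptor that takes up cholesterol from lipoproteins, lay at −1.33 ± 0.44 and Fdx1, the electron donor of side-chain cleavage, at −1.08 ± 0.37. These 3 genes and Lhcgr, the luteinising hormone receptor, were the 4 that were lower when adjusted over the list alone. Lhcgr was measured on 2 of 4 DEHP arrays and averaged 2.05-fold lower, where the bound equals the estimate (limma adjusted p = 0.866 over all genes). Another probe of Lhcgr was at −0.84 and did not pass. Cyp11a1, the side-chain cleavage enzyme (−0.79 ± 0.34), and Hsd3b1, a later enzyme (−0.48 ± 0.33), did not pass, and Nr5a1, the factor that drives these genes, was at 0.23 ± 0.24.

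Fetal Leydig cell markers other than enzymes were lower as a list with DEHP (median −0.30, adjusted p = 0.00622; adjusted p = 0.150 with an estimated correlation). Vcam1, an adhesion receptor (−0.61 ± 0.24), Nr0b1, a repressor of steroid genes (−0.60 ± 0.21), and Inha, an inhibin subunit (−0.53 ± 0.20), led it, while Insl3, the hormone of testis descent, was at −0.27 with values on 2 control arrays. Fatty acid synthesis genes were lower (adjusted p = 0.000152; adjusted p = 0.150 with an estimated correlation), with Scd, the stearoyl-CoA desaturase, at −1.17 ± 0.19 (adjusted p = 0.106). Oxidative stress and xenobiotic response genes were lower, with Gsta2, a glutathione transferase, at −2.70 ± 0.49 (list adjusted p = 0.0218; adjusted p = 0.150 with an estimated correlation). Sertoli cell markers were higher by a median of 0.07 (adjusted p = 0.0291; adjusted p = 0.204 with an estimated correlation), with Amh, the anti-Müllerian hormone, at 0.41 ± 0.18. Gonocyte markers were higher by 0.11 (adjusted p = 0.0291; adjusted p = 0.262 with an estimated correlation), with the RNA-binding germ cell gene Elavl2 at 0.48 ± 0.25 and the helicase Ddx4 at 0.21 ± 0.15.

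In the main fit no difference was seen with DEHP in peritubular and interstitial cell, endothelial cell, macrophage and leukocyte, erythroid, and mesonephric duct and epididymal markers, fatty acid oxidation and PPAR alpha targets, immediate early genes, endoplasmic reticulum stress, cell cycle, and retinoid handling. Of these, the fatty acid oxidation list had a mean of −0.02 and a camera direction up. Leaving out a single array could put more lists past camera than the main fit did. The immediate early gene Ccn1, a matrix protein, stood apart at 0.98 ± 0.20 (adjusted p = 0.289). The adrenal cortex list had 4 measured genes, too few for a list test, and its Cyp11b1, the 11-hydroxylase, was at −2.15 ± 0.57 with DEHP. Ppp1ca, a phosphatase subunit, was the only gene that passed over all genes, at a mean of 6.16 against 5.31 and with values on 2 of 4 control arrays, the others being marked as outliers. The limma test gave 592 genes at unadjusted p under 0.05, against 1198 expected by chance. The self-test recovered 64.2% of genes simulated at 2-fold with independent noise alike on all arrays, which does not give the power on these arrays. With the arrays of the 2 groups alone 15 genes passed, among them Star (adjusted p = 0.0282), Scarb1 (adjusted p = 0.0281), Tm7sf2 (adjusted p = 0.0158), Scd (adjusted p = 0.0159), Gsta2 (adjusted p = 0.00156) and Cyp11b1 (adjusted p = 0.0159), while 5 of 35 ways to split the 8 arrays, the real one among them, gave as many as the 7 lists past camera.

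The cholesterol, steroidogenesis and Leydig lists were lower with MEHP too, with more spread between its arrays than with DEHP. MEHP 3 lay close to control 2 (1.28 times the spot noise) and MEHP 4 to DEHP 3 (1.37 times), and whether these arrays held RNA of the MEHP litters was not settled. All 21 cholesterol genes lay below control (median −0.44, mean −0.54, adjusted p = 1.0e-18; adjusted p = 0.0241 with an estimated correlation), 15 of them lower when adjusted over the list alone. Tm7sf2 was at −1.33 ± 0.33, Cyp51 at −0.93 ± 0.25, Ebp at −0.79 ± 0.22, Idi1 at −0.74 ± 0.19 and Dhcr7, the last step of the Kandutsch-Russell pathway, at −0.69 ± 0.17. Steroidogenesis genes were lower (median −0.41, adjusted p = 3.6e-06; adjusted p = 0.110 with an estimated correlation), as were the fetal Leydig cell markers other than enzymes (median −0.42, adjusted p = 0.00184; adjusted p = 0.110 with an estimated correlation). Of 35 ways to split the MEHP and control samples, 21, the real one among them, put at least 3 lists past camera at its preset correlation. Star averaged 1.62 ± 1.64 (n = 3) against 3.30 ± 0.25 in control (n = 4), with −0.10 and −0.03 on MEHP arrays 1 and 2, 1.71 on array 4 and 3.21 on array 3. Cyp11a1 (−1.07 ± 0.37), Fdx1 (−1.04 ± 0.40), Scarb1 (−1.003 ± 0.48), Hsd3b1 (−0.75 ± 0.36) and Insl3 (−0.49 ± 0.47) had the same spread, and none passed. With MEHP arrays 3 and 4 left out, a choice made after the data were seen, MEHP is n = 1 with no spread of its own, and Star was at −3.36, Scarb1 at −2.61, Cyp11a1 at −2.41, Hsd3b1 at −2.08 and Insl3 at −1.99.

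Over all genes 231 changed with MEHP, 225 higher and 6 lower, and 97 of them by at least 2-fold. Scd fell (−1.10 ± 0.20, adjusted p = 0.00841), as did Gdf6, a bone morphogenetic protein (−0.98 ± 0.19), and Rdh11, a retinal reductase (−0.78 ± 0.16). Eprs, a tRNA synthetase (1.06 ± 0.18), Or9i1b, an olfactory receptor (1.05 ± 0.22), Nudt9, which cleaves ADP-ribose (1.03 ± 0.23), Actc1, the cardiac actin (0.98 ± 0.18), Or8b59, another olfactory receptor (0.90 ± 0.12), and Mapk8ip3, a kinase scaffold (0.79 ± 0.18), rose. The probe chosen for Supt16h, a histone chaperone subunit, rose by 1.35 ± 0.19, while 2 other probes of that gene were at 0.09 and 0.24. Only 34 of the 231 genes have a symbol, 196 of the 225 higher genes have none, and their median was 0.785 to 1.03 above control on each MEHP array. Gsta2 was at −2.27 ± 0.53 (adjusted p = 0.0520), Pax2, a duct transcription factor, at 0.54 ± 0.13 (adjusted p = 0.0840), Aldh1a2, which makes retinoic acid, at 0.94 ± 0.32 and Cebpb at −0.57 ± 0.18. The median and mean differed in sign for the Sertoli (0.12 and −0.01), gonocyte (0.06 and −0.01) and immediate early lists (0.02 and −0.03) and by less for the macrophage list, none of which passed, and no other list differed. The count is 116 with the arrays of the 2 groups alone and 3754 with arrays weighted, and the most among the other 34 ways to split the same arrays was 105.

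The steroid and cholesterol genes that were lower with DEHP lay near control with TOTM. Star was at 0.05 ± 0.46 from control, Cyp11a1 at 0.24 ± 0.34, Hsd3b1 at −0.12 ± 0.33, Scarb1 at −0.35 ± 0.44 and Insl3 at 0.06 with values on 2 control arrays. The cholesterol list had a median of −0.02 (adjusted p = 0.9753) and a mean per litter pool of 1.41 ± 0.08 against 1.46 ± 0.14 (n = 4 each), and steroidogenesis a median of 0.05 (adjusted p = 0.337). Within the cholesterol list Cyp51 was at −0.49 ± 0.24, Insig1 at −0.46 ± 0.27 and Nsdhl at 0.29 ± 0.12. Gonocyte markers were higher as a list (median 0.18, adjusted p = 0.0242; adjusted p = 0.7505 with an estimated correlation), with Tdrd1, which guards the germline against transposons, at 0.72 ± 0.24, Dnmt3l, a methylation cofactor, at 0.72 ± 0.49 and Tex101, a germ cell surface protein, at 0.39 ± 0.20. None of the other 16 lists passed, and the median and mean of the oxidative stress list (−0.12 and −0.02) lay opposite to its camera direction. Of 35 ways to split the TOTM and control arrays, 26, the real one among them, put at least 1 list past camera. Median and mean differed in sign for the endothelial (−0.01 and 0.05) and cell cycle lists (−0.01 and 0.02), and for endoplasmic reticulum stress (0.01 and −0.01).

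Among single genes 5 changed with TOTM, 1 higher and 4 lower, and 0 to 2 did when any 1 array was left out. Hnrnpa1, a splicing regulator, fell by 0.79 ± 0.13 (adjusted p = 0.0499), with 2 other probes at −0.53 and −0.21 that did not pass. Ppp1ca rose from 5.31 to 6.12 and Oaz1, the antizyme of polyamine synthesis, fell from 7.38 to 6.54 (adjusted p = 0.0499), each with values on 2 control arrays. Just beyond the threshold lay Tcf4, a helix-loop-helix factor (−1.10 ± 0.18, adjusted p = 0.0545), Nr2f2, a nuclear receptor of interstitial cells (−1.02 ± 0.18, adjusted p = 0.0551), Zfp36l2, which promotes mRNA decay (−0.76 ± 0.13), Klhl24 (−0.73 ± 0.12) and Mmp14, a matrix protease (−0.70 ± 0.12). Amh was at 0.53 ± 0.18, the Sertoli gene Cst12 at 0.73 ± 0.21, Nr5a1 at 0.57 ± 0.24 and Por, the reductase that serves the P450 enzymes, at 0.47 ± 0.22. The limma test gave 1966 genes at unadjusted p under 0.05 against 1198 expected. The count of 5 ranged from 0 with median scaling to 106 with outlier spots kept. The self-test, with its independent noise alike on all arrays, recovered 53.7% of genes simulated at 2-fold, which does not give the power here.

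EHO gave 5937 changed genes, 1547 higher and 4390 lower, a count that depends on the fit. With median scaling the balance turned to 5614 higher and 2637 lower. The count was 3 with the arrays of the 2 groups alone, 223 without EHO arrays 1 and 2, 699 without control array 1 and 10443 without EHO array 4, and 4 of 35 ways to split the 8 arrays, the real one among them, called as many. Of the changed genes 2343 were well above background on every array of both groups, and among these 1490 were higher and 853 lower. The genes below are therefore examples whose adjusted p rests on variance pooled over all 5 groups.

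Among the genes that rose with EHO were Dusp8, a phosphatase of stress kinases (2.05 ± 0.52), Plekhq1 (1.85 ± 0.52), Cx39, a connexin (1.74 ± 0.39), Wnt11, a secreted signal (1.65 ± 0.40), Mixl1 (1.62 ± 0.23), Hes7 (1.59 ± 0.40) and Calr, a calcium-binding chaperone (1.46 ± 0.28). Ctrb1, a digestive protease precursor (−1.45 ± 0.45), Magea10, a germ cell antigen (−1.23 ± 0.25), Ly6g6e (−1.13 ± 0.32), Akr1c2, a steroid-reducing enzyme (−1.12 ± 0.27), and Camk4, a calcium-dependent kinase (−1.11 ± 0.31), fell, though Ly6g6e was at −2.32 and −1.80 on EHO arrays 1 and 2 against −0.45 and −0.42 on arrays 3 and 4, and Akr1c2 was likewise lowest on arrays 1 and 2. Of 13 steroidogenesis genes 1 fell and 12 did not pass (median −0.33, list adjusted p = 0.900). That gene was Lhcgr, at least 1.72-fold lower and measured on 1 of 4 EHO arrays, and its sign turned with normexp background correction. Averaged over the list, each EHO litter pool lay below every control pool for steroidogenesis (−0.29, 95% interval −0.68 to 0.10, exact permutation p = 0.0286, n = 4 each) and for gonocyte markers (−0.27, −0.51 to −0.04, exact permutation p = 0.0286), where EHO 1 was at −0.03 against 0.48 to 0.60 on EHO 2 to 4. The means of the Sertoli (−0.25, −0.46 to −0.04) and oxidative stress lists (−0.28, −0.48 to −0.09) also lay below control, so this was not particular to steroidogenesis, and these tests were chosen after the data were seen. For Sertoli markers much of this came from EHO 1, at 0.36 against 0.80 to 1.02 on EHO 2 to 4. Star was at −0.58 ± 0.46, Scarb1 at −0.85 ± 0.44, Hsd3b1 at −0.57 ± 0.33, Cyp11a1 at −0.17 ± 0.34 and Insl3 at 0.06 with values on 2 control arrays. None of 21 cholesterol genes passed (median −0.10, list adjusted p = 0.996).

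Peritubular and interstitial markers had 3 of 10 genes higher with EHO, Nr2f2 (0.58 ± 0.18), the matrix gene Lum (1.09 ± 0.35) and the filament gene Des (0.61 ± 0.21), with a list adjusted p = 0.0685. Nr2f2 was at 3.71 on EHO 1 and at 2.80 to 2.95 on EHO 2 to 4. Of 20 Sertoli markers Cdkn1b, a cell cycle inhibitor (0.98 ± 0.25), and Gata4 (0.37 ± 0.11) rose and Kitlg fell at least 2.21-fold, measured on 2 of 4 EHO arrays. Of 16 gonocyte markers 3 fell, among them Kit, its receptor, at least 2.13-fold and on 2 EHO arrays. Of 12 retinoid handling genes 3 rose, such as Aldh1a2 (0.91 ± 0.29), and 3 fell, such as Aldh1a3, at least 1.88-fold and measured on 3 EHO arrays. Jun (0.50 ± 0.15), Junb (0.61 ± 0.17), the topoisomerase Top2a (0.54 ± 0.16), the keratin Krt19 (0.85 ± 0.19), the Leydig progenitor gene Dlk1 (0.62 ± 0.18) and the endothelial gene Emcn (0.51 ± 0.18) rose. From the same lists Fos fell at least 1.47-fold and was measured on 2 of 4 EHO arrays, Egr3 at least 1.16-fold and on 1, and Flt1, a growth factor receptor, at least 1.28-fold and on 0. Prlr, the prolactin receptor, fell at least 1.54-fold and Gata3 at least 1.66-fold, each measured on 2 EHO arrays. The falls of Kitlg, Kit, Aldh1a3, Fos, Egr3, Prlr and Gata3 came mostly from EHO arrays 1 and 2, where Kitlg was at −4.52 and −3.23 against −1.50 and −1.57 on arrays 3 and 4. None of the 17 lists passed by camera, and the cholesterol, Leydig, Sertoli, endothelial, macrophage, duct, immediate early, oxidative stress and retinoid lists had a mean below 0 and a camera direction up.

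**Figure D2:**
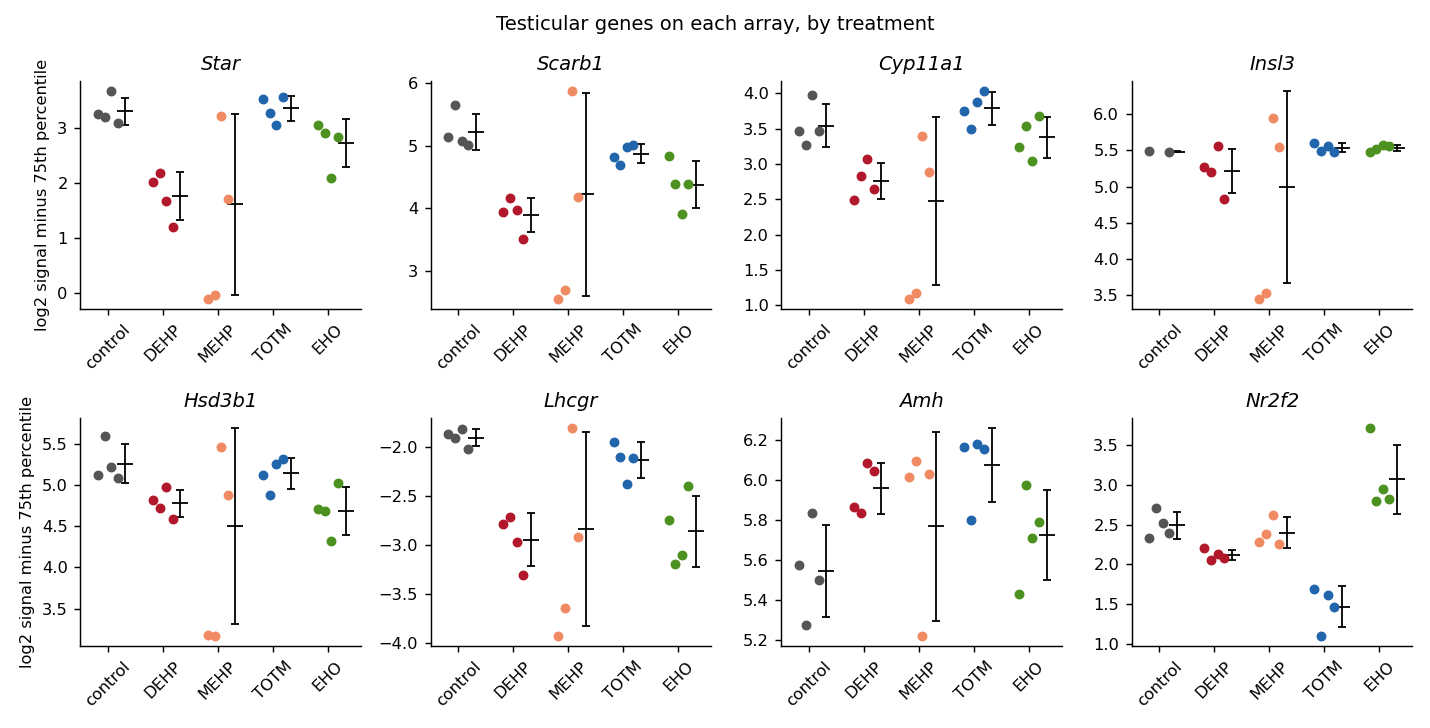
Log2 level of selected steroidogenic, cholesterol and cell marker genes on each of the 20 arrays, relative to the 75th percentile of the array. Arrays are grouped by compound, missing points are spots marked as outliers, and bars are the mean and SD.

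**Figure D3:**
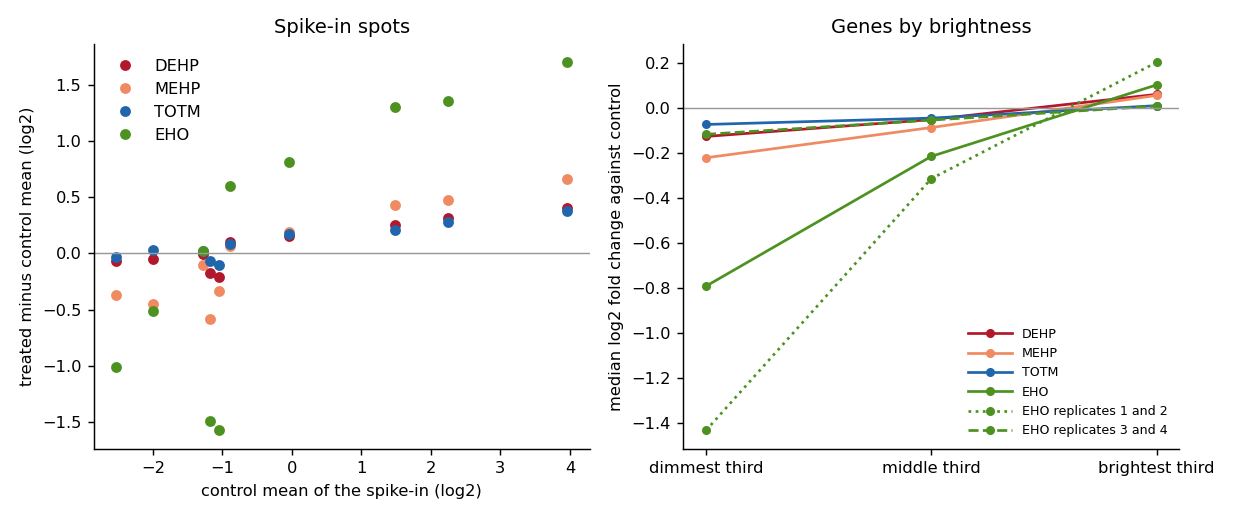
Left, log2 difference of each spike-in from the control arrays, by its control level. Right, median log2 fold change of genes by brightness, with EHO replicates 1 and 2 and replicates 3 and 4 also drawn apart.

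At the matched dose of 500 mg/kg the cholesterol list separated TOTM and EHO from DEHP. The list mean per litter pool was 0.45 higher with TOTM than with DEHP (95% interval 0.24 to 0.66, exact permutation p = 0.0286, n = 4 each) and 0.36 higher with EHO than with DEHP (0.15 to 0.57, exact permutation p = 0.0286), though the camera call for EHO against DEHP was lost with an estimated correlation (adjusted p = 0.220). MEHP and DEHP differed by −0.03 (−0.26 to 0.19), TOTM and MEHP by 0.48 (0.26 to 0.71), EHO and MEHP by 0.39 (0.17 to 0.62), and EHO and TOTM by −0.09 (−0.30 to 0.11). The cholesterol list mean was 0.766, 0.783 and 0.796 on MEHP 1, 2 and 4, below every DEHP array (0.847 to 1.14), and 1.21 on MEHP 3, above them all. The sizes of the MEHP differences thus depend on MEHP 3, and with it MEHP is not separated from DEHP. MEHP 3 still lay below every TOTM array (1.31 to 1.49) and every EHO array (1.27 to 1.39). For steroidogenesis TOTM lay 0.51 above DEHP (0.12 to 0.90) and EHO 0.16 above it (−0.23 to 0.55). These list means per pool were chosen after the data were seen.

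TOTM against DEHP gave no single gene past the limma test and 732 at unadjusted p under 0.05, with 1214 expected by chance. All 22 cholesterol genes lay higher with TOTM (adjusted p = 8.7e-28; adjusted p = 0.00440 with an estimated correlation), and 14 were higher when adjusted over the list alone, such as Tm7sf2 (1.46 ± 0.30), Ebp (0.78 ± 0.20) and Dhcr7 (0.63 ± 0.16). All 11 Leydig markers lay higher (adjusted p = 3.7e-05; adjusted p = 0.0429 with an estimated correlation). Steroidogenesis genes were higher (adjusted p = 8.1e-08; adjusted p = 0.0547 with an estimated correlation), with Star at 1.58 ± 0.46, Cyp17a1 at 1.06 ± 0.39, Cyp11a1 at 1.03 ± 0.34 and Scarb1 at 0.98 ± 0.44. In 9 of 35 ways to split the TOTM and DEHP arrays, the real one among them, all 3 of these lists passed camera at its preset correlation. Fatty acid synthesis was higher, with Scd at 1.12 ± 0.19 (list adjusted p = 0.00805; adjusted p = 0.342 with an estimated correlation), oxidative stress genes were higher (adjusted p = 0.0149; adjusted p = 0.122 with an estimated correlation) and immediate early genes lower (adjusted p = 0.00256; adjusted p = 0.285 with an estimated correlation), though the list mean was 0.59 on DEHP 4 and −0.01 to 0.16 on DEHP 1 to 3.

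TOTM against MEHP had 369 changed genes, 25 higher and 344 lower. Among cholesterol genes Dhcr7 (0.85 ± 0.17), Fdft1 (0.57 ± 0.12), Nsdhl (0.55 ± 0.13) and Mvd (0.55 ± 0.13) were higher with TOTM, and so was Scd (1.04 ± 0.20). Nr2f2 was lower (−0.93 ± 0.20), as were Aldh1a2 (−1.39 ± 0.32), Pax2 (−0.55 ± 0.13) and the deacylase Sirt5 (−1.24 ± 0.23). The cholesterol (adjusted p = 3.8e-11), steroidogenesis (adjusted p = 8.4e-06) and Leydig lists (adjusted p = 0.00341) were higher with TOTM, and all 3 calls were lost with an estimated correlation (adjusted p = 0.137 for the cholesterol list). MEHP against DEHP had 274 changed genes, 272 higher and 2 lower, among them Actc1 (1.07 ± 0.18), Sirt5 (1.08 ± 0.23), the tight junction gene Cldn9 (1.02 ± 0.20) and Pax2 (0.58 ± 0.13), with Rdh11 lower (−0.68 ± 0.16). Star differed by −0.15 ± 0.50 and Scarb1 by 0.33 ± 0.48 between these 2 groups, and none of the 17 lists passed. These MEHP means join unlike arrays, so they do not show that the 2 groups were alike. The steroidogenesis list mean was 1.14 and 1.22 on MEHP 1 and 2, 2.38 on MEHP 3 and 2.01 on MEHP 4. With DEHP it was 1.88 to 2.12.

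EHO against DEHP had 1622 changed genes, 886 higher and 736 lower, with 238 when the fit held the arrays of the 2 groups alone. Of 22 cholesterol genes 6 were higher with EHO, among them Tm7sf2 (1.15 ± 0.30), Cyp51 (0.95 ± 0.24), Idi1 (0.94 ± 0.18) and Sqle (0.68 ± 0.16) (list adjusted p = 9.5e-08; adjusted p = 0.220 with an estimated correlation). Nr2f2 (0.95 ± 0.18), the collagens Col1a1 (0.88 ± 0.22) and Col3a1 (0.61 ± 0.15), Scd (0.75 ± 0.19) and Elovl6, a fatty acid elongase (0.71 ± 0.15, another probe at 0.49 not passing), were higher and the water channel Aqp11 lower. The peritubular (adjusted p = 0.000888; adjusted p = 0.220 with an estimated correlation), fatty acid synthesis (adjusted p = 0.000299; adjusted p = 0.233 with an estimated correlation) and erythroid lists (adjusted p = 0.0199; adjusted p = 0.514 with an estimated correlation) were also higher. Star was at 0.95 ± 0.46 (adjusted p = 0.139).

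EHO against MEHP had 73 changed genes, 21 higher and 52 lower, among them Calr (1.49 ± 0.30), the receptor subunit Gabrq (1.16 ± 0.22), Junb (1.08 ± 0.19) and Aqp11 (−0.92 ± 0.15), but 0 with the arrays of the 2 groups alone. The lists higher with EHO were cholesterol, steroidogenesis, Leydig, peritubular, erythroid, fatty acid synthesis, endoplasmic reticulum stress and cell cycle, and all 8 were lost with an estimated correlation (adjusted p = 0.167 for cholesterol). EHO against TOTM had 5244 changed genes, 2023 higher and 3221 lower, with 923 from the arrays of the 2 groups alone and 1579 to 10921 with 1 array left out. Median scaling gave 3985 higher and 1985 lower, and 4 of 35 splits, the real one among them, called as many. Nr2f2 (1.60 ± 0.18), Pcdh7, a protocadherin (1.92 ± 0.21), Alcam, an adhesion molecule (1.77 ± 0.20), Col1a1 (1.06 ± 0.22) and the embryonic globin Hbe2 (1.23 ± 0.25) were higher with EHO. Cst12 (−1.01 ± 0.21), Aqp11 (−1.22 ± 0.14) and the piRNA genes Mael (−0.56 ± 0.17) and Piwil2 (−0.47 ± 0.14) were lower. The peritubular list was higher (adjusted p = 0.00503; adjusted p = 0.540 with an estimated correlation), as was the erythroid list (adjusted p = 0.00911; adjusted p = 0.703 with an estimated correlation).

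**Figure D4:**
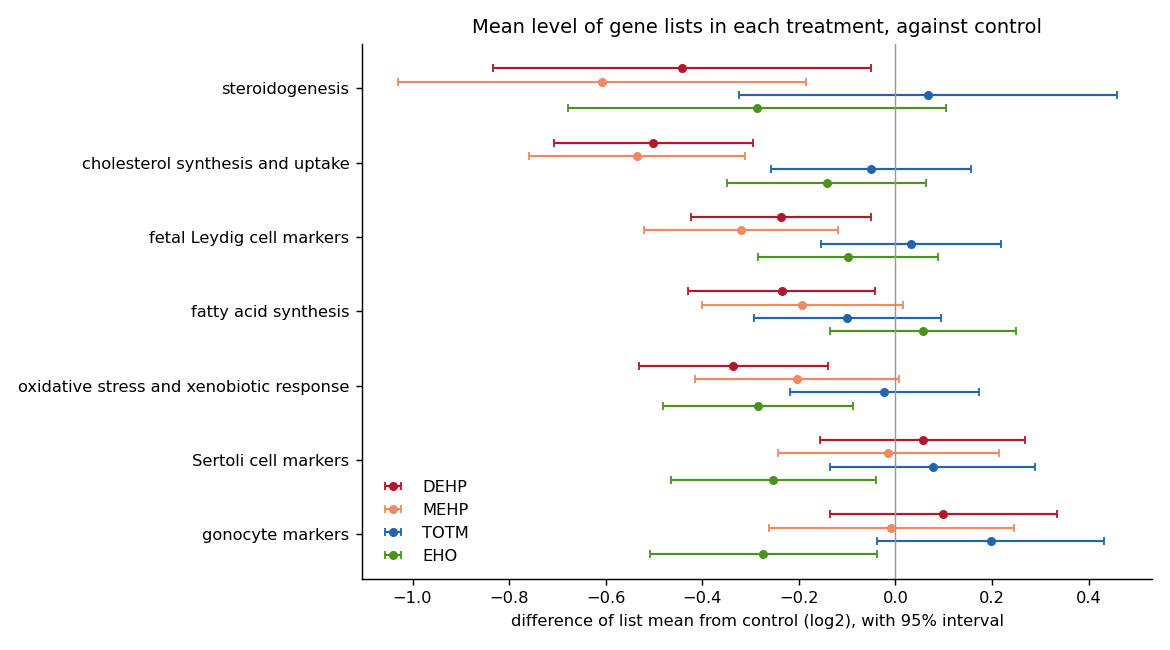
Difference of the mean log2 level of 7 gene lists from control with each compound. Bars are 95% intervals from variance pooled over the 5 groups.

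MEHP and EHO shared 174 higher and 4 lower genes against the same 4 controls. Independent calls would share 14.5 and 1.10. With the controls split 2 and 2 between the comparisons the shared count averaged 68.7 (54 to 91 over 6 assignments). The fold changes of MEHP and EHO correlated at r = 0.644 with a covariance of 0.116, while 50 simulations of unchanged groups with shared controls gave a mean r of 0.407 (−0.509 to 0.905) and a covariance of 0.0241. Over all pairs of compounds 187 calls were shared, and 178 of them were those of MEHP and EHO. None of these comparisons covers an effect of the slides. The genes higher with MEHP had a median of 1.06 in MEHP 3 minus control 2, so the shared calls may be a slide effect.

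The authors' deposited table lists 1004 probes for DEHP, 3827 for MEHP, 3298 for TOTM and 4210 under the heading EH, which is assumed here to be the compound labelled EHO on the arrays. The direction here matched the authors' deposited table for 100% of its tested DEHP and TOTM probes, 96.8% for EH and 89.9% for MEHP. Both sets of values come from the same arrays, so a shared direction is no independent check. Of the tested probes, 1 of 764 passed here for DEHP, 2 of 3038 for TOTM, 78 of 3588 for MEHP and 1903 of 3929 for EH. The authors' p-values run up to 0.00999 in each block, with folds down to 1.07 for DEHP, while a call here needs a limma adjusted p under 0.05. These thresholds are unlike, so the counts are no test of the authors' lists. The authors' deposited table gives a signed fold change with DEHP of −2.75 for Star, −2.70 for Scarb1, −1.68 for Cyp11a1, −3.05 for Tm7sf2, −5.77 for Gsta2 and −1.46 for Cyp17a1. For MEHP the authors' deposited table gives −9.9 for Star, −6.6 for Scarb1, −5.1 for Cyp11a1, −4.6 for Insl3 and −4.4 for Cyp17a1. For TOTM the authors' deposited table gives −2.03 for Nr2f2, −1.32 for Scarb1, 1.45 for Cyp17a1 and 1.55 for Amh, and for EH −1.52 for Star and −2.01 for Scarb1. The MEHP folds of the authors' deposited table lie a median of 0.0574 log2 from those of MEHP array 1 against control arrays 1, 2 and 4 (r = 0.951), the closest of the subsets tried after the data were seen. The distance from the authors' deposited table was 0.0611 for MEHP arrays 1 and 2 (r = 0.951) and 0.251 for all 4 MEHP and 4 control arrays (r = 0.814).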

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

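The rule for far values was fixed before the data were examined, and the look at the spike-ins and at bright and dim genes was chosen after the result was seen. Among 118 groups of 4 values tested, 6 held a value far from the other 3, and chance gives about 1 in 20. These were the endoplasmic reticulum stress list mean of DEHP 4 at 1.86, the percent of spots well above background of DEHP 3 at 73.5%, the Amh level of TOTM 2 at 5.80, the 75th percentile of TOTM 4 at 8.32 log2, the Nr2f2 level of EHO 1 at 3.71 and the oxidative stress and xenobiotic response list mean of EHO 4 at 0.55. With 6 of 118 the number of such values is what chance gives.

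The spike-in probes, which receive the same amount of transcript on every array, were not used in the fit. The 5 brightest of them lay higher on every EHO array than on every control array, by 0.60, 0.81, 1.31, 1.35 and 1.70 log2 from the dimmest to the brightest. They were also above every control array on MEHP 1 and 2, with the brightest at 5.10 and 5.16 against 4.36 at most in control. On MEHP 3 the brightest was at 3.62 and on control 2 at 3.71, and on MEHP 4 at 4.59 and on DEHP 3 at 4.52. The 5 brightest averaged 1.19 above control on EHO 1 and 2 and 1.12 on EHO 3 and 4, while the 5 dimmest averaged −1.87 on EHO 1 and 2 and 0.0396 on EHO 3 and 4.

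Chance splits were planned before the data were examined. Each pair of groups was split in 35 ways, the real way included, and the limma count was taken each time. For DEHP against control the real count of 1 was reached by 1 split, the real one, and the highest other was 0. For MEHP against control it was 231, reached by 1 split, and the highest other was 105. For TOTM against control it was 5, reached by 1 split, and the highest other was 0. For MEHP against DEHP it was 274 (1 split, highest other 3), for EHO against DEHP 1622 (1 split, highest other 1) and for TOTM against MEHP 369 (1 split, highest other 0). No other split gave as many for these counts, which is 1 in 35, the smallest share this test can give. The test was not adjusted for the number of comparisons, and it cannot exclude the slide effect. For DEHP against control the split test covers 1 gene, Ppp1ca, with values on 2 control arrays, and limma gave 592 genes at unadjusted p under 0.05 against 1198 expected by chance. For TOTM against control the count of 5 was 0 with median scaling.

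For EHO against control the real count of 5937 was reached by 4 splits of 35, and the highest other was 8124. For EHO against TOTM it was 5244 (4 splits, highest other 6870), and for EHO against MEHP 73 (6 splits, highest other 7119). Chance cannot be excluded for these 3. For TOTM against DEHP it was 0 (35 splits, highest other 0), and since every split reaches 0 that test says nothing. The splits with many genes point to a structure of the samples: for EHO against MEHP the highest set EHO 3 and 4 with MEHP 1 and 4 against EHO 1 and 2 with MEHP 3. For lists the real numbers past the test were 7 for DEHP (5 splits, highest other 12), 3 for MEHP (21 splits, highest other 12), and 1 for TOTM (26 splits, highest other 9). For EHO it was 0 (35 splits, highest other 9), which every split reaches, so that test says nothing either. For TOTM against DEHP all 3 of the steroidogenesis, cholesterol and Leydig lists passed in the real split and in 9 of 35 splits in all, with 3 the highest other. Chance cannot be excluded for the number of lists past camera at its preset correlation in the other 4 tests, and list splits were not run for the other comparisons between compounds.

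MEHP 3 lay close to control 2 (1.28 times the spot noise) and MEHP 4 to DEHP 3 (1.37 times), closer than any other pair of 2 groups (1.60 times), and the test of litters that responded alike and the medians of the 225 genes were chosen after the result was seen. If the same labelled RNA had been put on both slides, the 2 differences would share the slide effect. They correlated at 0.696, above the highest of 95 other combinations at 0.646, so this prediction was met. The other combinations hold differences between the same slides, and these 2 pairs were picked as the closest. They would tend to rank highest whatever made them close, so the correlation cannot decide. A shared technical state of those arrays met its prediction: with 3 principal components taken out, the distance to the partner was 1.01 times that to the nearest other array, against 0.571 and 0.754 with none out. Those components were computed from the same arrays, and control 2 (35.1) and MEHP 3 (41.4) lie far out together on the first. Taking them out removes a shared profile of any cause, so this test cannot decide. Litters of 2 groups that responded alike would make such closeness common, and 0 of 29 other pairs of 1 group were as close, but the nearest was only 1.06 times farther, so this cannot be told. The 225 genes higher with MEHP had a median of 1.06 in MEHP 3 minus control 2 and 0.914 in MEHP 4 minus DEHP 3, so they may be a slide effect as well as a response to MEHP.

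Genes lower with EHO were mostly dim, with 62.3% of them among the dimmest of 3 equal parts of the genes against 7.69% of the genes that were higher; the test on EHO 3 and 4 was planned with a bound of 0.1, and the other tests here were chosen after the result was seen. The dimmest part lay at −1.64 log2 from the brightest with EHO 1 and 2 and at −0.126 with EHO 3 and 4. The latter misses the bound, so by the planned rule arrays 1 and 2 alone are not the cause. It lies inside the range of the other compounds, though (−0.277 to −0.0836). The 5 dim spike-ins averaged −1.87 against control on EHO 1 and 2 and 0.0396 on EHO 3 and 4. The 5 bright ones averaged 1.19 and 1.12 there, so relative to them the dim ones were low on both pairs of arrays. Genes place most of the lowered dim end on EHO 1 and 2, but with these spike-ins a lowered dim end on the whole slide stays open. With EHO 1 and 2 left out 223 genes differed from control. A biological cause was not separated from the slide for those, since 1 slide held all EHO arrays.

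Steroid and cholesterol genes were lower with DEHP, and these 2 tests were chosen after the result was seen. Star minus Hsd3b1 fell by 1.05 with DEHP (exact permutation p = 0.0286, the smallest of 70 splits), but the 2 genes were picked once their changes were known, so fewer fetal Leydig cells as the whole cause stay open. Adrenal tissue in the control pools could raise Cyp11b1, and Cyp21a1, an adrenal enzyme, was well above background on 1 of 4 control arrays and on 1 of 4 DEHP arrays, with means of −3.23 in control and −3.02 with DEHP. The Cyp21a1 means go against adrenal tissue as the explanation, but at so dim a level they cannot decide. Means of other adrenal genes go with it, being lower with DEHP than in control. Mc2r was at −3.97 against −3.16, well above background on 0 DEHP and 2 control arrays. Cyp11b3 was at −2.75 against −2.54, Cyp11b2 at −2.45 against −2.003 and Akr1b7 at −1.47 against −1.01. Adrenal tissue in the control pools therefore stays open too.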

How the results depend on the processing

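The settings in this paragraph were planned before the data were examined, and the values are counts of genes past the limma test unless lists are named. With normexp and quantile normalization the counts were 18 for DEHP, 371 for MEHP and 88 for TOTM against control, 749 for TOTM against MEHP and 582 for EHO against MEHP, with 5 lists for MEHP and 0 for TOTM. With quantile normalization alone they were 11 for DEHP and 52 for TOTM against control, 614 for TOTM against MEHP and 337 for EHO against MEHP, with 5 lists for MEHP and 0 for TOTM. With median scaling they were 0 for DEHP, 93 for MEHP and 0 for TOTM against control, 72 for MEHP against DEHP, 58 for TOTM against MEHP and 6 for EHO against MEHP. Without a filter they were 0 for DEHP, 1 for TOTM and 10491 for EHO against control. With probes well above background on all 20 arrays they were 3 for DEHP, 47 for TOTM and 2139 for EHO against control, 585 for TOTM against MEHP, 155 for EHO against MEHP and 3213 for EHO against TOTM, with 0 lists for TOTM. Over all probes they were 2 for TOTM against control and 114 for EHO against MEHP, and with a trended robust variance 20 for TOTM against control. With the arrays of the 2 groups alone they were 15 for DEHP, 116 for MEHP, 2 for TOTM and 3 for EHO against control, 8 for TOTM against DEHP, 238 for EHO against DEHP, 240 for TOTM against MEHP, 0 for EHO against MEHP and 923 for EHO against TOTM, with 2 lists for TOTM. At 2-fold or more they were 0 for DEHP, 97 for MEHP, 0 for TOTM and 2896 for EHO against control, 108 for MEHP against DEHP, 433 for EHO against DEHP, 123 for TOTM against MEHP, 39 for EHO against MEHP and 1965 for EHO against TOTM. A threshold on fold can only lower a count, and for the other settings the cause was not tested. With an estimated correlation 1 list passed for DEHP, 1 for MEHP, and 0 for TOTM, and with fry 1 for DEHP and 0 for TOTM. Counts between compounds cover only the steroidogenesis, cholesterol and Leydig lists over 6 comparisons. They were 10 with the settings of the report, 2 with an estimated correlation and 6 with fry. With the controls split the shared calls averaged 68.7.

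Replicate number as a block gave 0 genes for DEHP, 8 for TOTM and 2235 for EHO against control, 2 for TOTM against DEHP, 919 for EHO against DEHP, 42 for EHO against MEHP and 2854 for EHO against TOTM. The numbers do not pair the samples: in 0 of 10 pairs of groups did all arrays with the same number correlate above 0.1, and their mean correlation was −0.0321 against 0.0195 for other numbers. A block of slide or scan batch was not run, because each slide and scan holds 1 group and batch and group cannot be told apart.

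Leaving out 1 array at a time gave 0 to 6 genes for DEHP, 147 to 248 for MEHP, 0 to 2 for TOTM and 699 to 10443 for EHO against control. Between compounds it gave 171 to 289 for MEHP against DEHP, 0 to 0 for TOTM against DEHP, 551 to 8938 for EHO against DEHP, 187 to 395 for TOTM against MEHP, 0 to 3825 for EHO against MEHP and 1579 to 10921 for EHO against TOTM. For lists the ranges were 2 to 8 for DEHP, with 2 without control 3, 3 to 5 for MEHP, 0 to 3 for TOTM, 0 to 1 for EHO and 10 to 12 between compounds for the same 3 lists. For EHO against control the count was 699 without control 1, 1183 without control 4, 808 without EHO 1, 1029 without EHO 2, 9943 without EHO 3 and 10443 without EHO 4. The cause was not tested.

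The settings that follow were chosen after the data were seen. With MEHP 1 and 2 as separate samples the counts were 21 for TOTM against control, 715 for TOTM against MEHP and 392 for EHO against MEHP. With control 2 and MEHP 3 left out they were 6 for DEHP and 0 for TOTM against control, 6 for TOTM against DEHP, 207 for TOTM against MEHP and 1 for EHO against MEHP, with 5 lists for MEHP and 2 for TOTM. With outlier spots kept they were 78 for DEHP and 106 for TOTM against control, with 1 list for EHO. With arrays weighted they were 33 for DEHP, 3754 for MEHP, 80 for TOTM and 703 for EHO against control, 1872 for MEHP against DEHP, 57 for TOTM against DEHP, 955 for EHO against DEHP, 6745 for TOTM against MEHP, 1292 for EHO against MEHP and 2247 for EHO against TOTM, with 1 list for MEHP and 2 for TOTM. With the 75th percentile over probes detected on all arrays they were 9 for DEHP and 33 for TOTM against control, with 1 list for EHO. With MEHP 3 and 4 left out MEHP is 1 sample and the other groups supply all the spread, and the counts were 141 for MEHP against control, 80 for MEHP against DEHP, 127 for TOTM against MEHP and 4 for EHO against MEHP, with 6 lists for MEHP. With MEHP 1 and 2 left out together they were 169 for MEHP against control, 212 for MEHP against DEHP, 211 for TOTM against MEHP and 352 for EHO against MEHP. With EHO 1 and 2 left out they were 223 for EHO against control, 318 for EHO against DEHP, 19 for EHO against MEHP and 961 for EHO against TOTM. With the MEHP arrays out of the fit they were 13 for DEHP, 0 for TOTM and 3271 for EHO against control, 8 for TOTM against DEHP and 3370 for EHO against TOTM. The cause was not tested.

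The sign changed for 2 lists and 5 genes. The erythroid list for MEHP against DEHP had a median of −0.60 with MEHP 3 and 4 left out and MEHP at n = 1, and the cell cycle list for EHO against MEHP a median of 0.0133 with EHO 1 and 2 left out. With normexp the value of Lhcgr, EHO against control, was 0.0252 and that of Rarb, EHO against control, 0.0490. With median scaling it was 0.0483 for Hsd17b3, EHO against TOTM, 0.0786 for Fdft1, EHO against TOTM, and 0.0380 for Chac1, EHO against TOTM. The cause was not tested.

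Scaling moved the share of higher and lower genes. For EHO against control the main split of 1547 higher and 4390 lower became 5614 and 2637 with median scaling, 1819 and 2375 with normexp, 1990 and 2446 with quantile normalization and 793 and 5984 with the 75th percentile over detected probes. The median of all genes moved by 0.53, 0.16, 0.14 and −0.15 in turn, and with median scaling by 0.10 for DEHP and 0.17 for MEHP. For EHO against DEHP, 886 and 736 became 1540 and 623 with median scaling and 581 and 943 over detected probes. For EHO against TOTM, 2023 and 3221 became 3985 and 1985 with median scaling, 2334 and 2403 with normexp, 2596 and 2649 with quantile normalization and 1421 and 3612 over detected probes. For EHO against MEHP, 21 and 52 became 0 and 6 with median scaling, 268 and 314 with normexp, 157 and 180 with quantile normalization and 5 and 66 over detected probes. For TOTM against MEHP, 25 and 344 became 198 and 551 with normexp and 118 and 496 with quantile normalization. For MEHP against control, 225 and 6 became 309 and 62 with normexp and 293 and 43 with quantile normalization. For DEHP against control, 1 and 0 became 1 and 17 with normexp, 1 and 10 with quantile normalization and 1 and 8 over detected probes, and for TOTM against control 1 and 4 became 4 and 48 with quantile normalization and 2 and 31 over detected probes. The number of arrays and the share of spots above background, lowest with EHO at 46.1%, limit what dim genes can show.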

Other observations

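Adrenal, fatty acid and erythroid genes held differences not described above. With EHO the 2 adrenal cortex genes Akr1b7, an aldose reductase, and Cyp11b2, the aldosterone synthase, were lower, at least 2.51-fold and 1.40-fold, each measured on 2 of 4 EHO arrays. Most of this came from EHO arrays 1 and 2, where Cyp11b2 was at −4.94 and −4.95 against −2.12 and −2.29 on arrays 3 and 4, within or next to its control values. Cyp11b1 was at −1.04 ± 0.57 (adjusted p = 0.159). With TOTM Cyp11b1 was at 0.36 ± 0.57 and Akr1b7 at −0.36 ± 0.50, and with MEHP Cyp11b1 was at least 3.14-fold lower on average without passing. Elovl6 rose with EHO by 0.44 ± 0.15, for which another probe was at 0.20 (adjusted p = 0.362), and was at −0.41 ± 0.15 with TOTM (adjusted p = 0.519). Of the erythroid genes 4 of 9 were higher with EHO than with TOTM, among them Slc4a1, an anion exchanger (1.22 ± 0.34), for which another probe was at −0.21.

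On the control slide 397 spots were marked as outliers on all 4 arrays, 389 of them as non-uniform and 381 on no array of another slide, with a median signal at percentile 99.5. The spot of Cyp17a1 is among them. The control arrays had 539 to 551 outlier spots and the others 66 to 144. No spot was saturated.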
